A study of Mus musculus with 6 samples.

How the data were processed

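RNA sequencing was available for 6 samples of mouse ILC2s (group 2 innate lymphoid cells) from the colon, 3 treated with vehicle (Control) and 3 with toyocamycin, per the labels. The series text states 5 days of culture before treatment and 16 h of treatment. RNA was extracted with TRIzol and libraries were made by a standard Illumina protocol, per the labels' protocols, which name neither poly(A) selection nor ribosomal RNA removal. The dose of toyocamycin is not given in the sources used here. Nothing states that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

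The authors trimmed reads with cutadapt 4.7, ran FastQC and used the mouse genome build mm10, per the submitters' processing notes, which give no order or role for these tools. The aligner, the counting program, its strand setting, the treatment of reads that match several places and the annotation are not given in the sources used here. The deposited table is named for FPKM, but its values are a normalised signal of another kind: in each column every value is a whole multiple of the value of 1 read, and this step is the same for short and long genes. With a tolerance of 0.01 reads, 100% of the deposited values in each sample came out as whole reads. The values are therefore taken as reads per gene divided by 1 size factor per sample, and are called normalised read counts. The recovered factors run from 0.7572 to 1.1808, and median-of-ratios factors computed from the recovered reads are close to them (1.1071 against 1.1037 in Control replicate 1, for example). All 6 columns were matched to samples by the group letter and replicate number in their names.

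The table has 25865 genes, of which 7593 were at 0 in all samples. The recovered totals were 25.5 M, 27.0 M and 26.9 M reads in Control and 22.3 M, 36.7 M and 23.9 M in toyocamycin. At 3 reads per library, the smallest level treated as detectable, the normalised read count is 2.66 in Control and 3.38 in toyocamycin; a fold against a group at 0 is given as a lower bound against this floor. Such bounds and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging. Every pair within a group differed by more than counting noise (chi-square per degree of freedom 3.96 to 7.76), which does not tell separate cultures from repeat libraries of 1 culture. All 6 samples were kept separate, as labelled.

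Values were analysed as log2(normalised read count + 1), in genes with a mean of at least 1 over the 6 samples, which left 16223 genes. The pseudocount of 1 makes a log2 change understate the change of genes with few reads. Toyocamycin was compared with Control by a linear model in limma 3.58.1 with a mean-variance trend (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A second count required a log2 change of at least 1 in size. Folds in the text are ratios of group means, and log2 changes with their standard errors (SE) come from the model. Gene lists were tested with limma's camera, which compares a list with all other genes, at its preset correlation between genes of 0.01, adjusted over the 31 lists. The same test was run with the correlation estimated from the data, a weaker test that rests on 4 residual degrees of freedom. In addition, fry was run as a test of whether a list's members move, on balance, in 1 direction, without comparing them with other genes.

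The design, the gene lists, the rule for the genes named in the text and most alternatives were fixed before the data were examined. That design assumed FPKM values and named edgeR in place of limma should the table hold counts. The limma test was kept because the values turned out to be normalised and not raw counts. Since whole reads could be recovered, keeping limma can be read as a departure from that rule. The edgeR test was run as an alternative. The lists cover the unfolded protein response (XBP1s targets, reported RIDD substrates, ATF6 targets, the PERK-ATF4 integrated stress response), ILC2 identity, ILC2 cytokines and effectors, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, ribosome biogenesis, p53 targets, S phase and DNA replication, G2 and mitosis, replication-dependent histones, immediate early and short-lived transcripts, interferon-stimulated genes, apoptosis regulators, NRF2 targets, cholesterol synthesis and uptake, heat shock, autophagy and lysosome, and adenosine handling. A further 8 lists hold markers of T cells, ILC3s, NK cells and ILC1s, B cells and plasma cells, macrophages and dendritic cells, mast cells, epithelial cells, and fibroblasts and endothelial cells. Of 653 list entries, all 653 matched a symbol of the table, partly through older symbols. Mitochondrial mRNAs carry RefSeq names in the table (ND5 for mt-Nd5, for example).

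The rule named the 10 genes with the most positive and the 10 with the most negative log2 change among those past the threshold, with a mean of at least 5 in the higher group and no overlap between the groups, leaving out predicted gene models and pseudogenes. It also named 18 genes fixed in advance and up to 3 members of each list with the log2 change of greatest size. Further genes were chosen after their values were seen: Tph1, Osm, Lif, Calca, Il2ra, Ets1, Ltb4r1, Spcs2, Derl1, Pck2, Mdm2, Zmat3, Mcm2, Cdc45, Slc29a1, Ahcy, Fth1, Lamp1, Fos, Hspa8, COX1, COX2, Actb, H2bc4, Gzma, Rn45s, mt-Rnr1, mt-Rnr2 and the members of the symbol families under other observations.

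Gene positions are those of the RefSeq annotation of assembly GRCm38.p6, the assembly of build mm10, which holds 23889 of the table's symbols. GC content and length were found for 97.8% of the tested genes. Host genes of small RNA genes come from the GENCODE annotation of the same assembly. Reads from near-identical copies could be lost or moved between genes, depending on the counting. Low values of Gapdh and of some ribosomal protein and mitochondrial genes point to such losses, and those genes are uncertain.

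The alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5, equal sample totals, median-of-ratios scaling, quantile normalization, a replicate block, leaving out each sample in turn, limma without the trend, with robust moderation and with array weights, and for the lists an estimated correlation and fry. Equal totals stand for rescaling to a common sum (TPM in the design): they were set to the mean total, so that the pseudocount and the filter kept their meaning. Added after the data were seen were a correction for GC content and length (a smooth trend removed from each sample) and count tests on the recovered whole reads with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. Genes that DESeq2 gives no adjusted p for stayed out of its counts. Ranges of a list's adjusted p are over the alternatives that use camera at the preset correlation. The groups were also split in all 10 ways into 3 and 3 samples.

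The procedure was tested on simulated reads for 3 against 3 samples with the means and library sizes of this series. Over 15834 simulated genes, limma recovered 52% of 50 genes changed 1.25-fold, 76% of 50 changed 1.5-fold, and 100% of those changed 2-fold and 4-fold, with 11 false calls among 175. Of 20 random gene lists, camera called 0 there, with 1 planted list called at an adjusted p of 5.27e-99. The simulated dispersion was set and not estimated from these data, genes varied independently, and few were changed. In the real data 65.9% of genes were called changed, and estimated correlations within lists reached 0.457. The simulated lists therefore do not show how camera performs on the real ones. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No column of the table was left out.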

Results

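ILC2s are tissue-resident lymphocytes that make the type 2 cytokines IL-5 and IL-13. The cells came from the large intestine of C57BL/6 mice and grew for 5 days with IL-2, IL-7, IL-25 and IL-33, each at 10 ng/mL. They then received toyocamycin for 16 h or its vehicle, with no time recorded for the Control samples. Toyocamycin is an adenosine analogue known to inhibit the RNase activity of the stress sensor IRE1, which splices Xbp1 mRNA, and the processing of ribosomal RNA. The comparison asks how the transcriptome of activated ILC2s differed after exposure to the compound. It rests on 3 Control and 3 toyocamycin samples with 22.3 M to 36.7 M reads assigned to genes in each. Values are normalised read counts, given as mean ± SD (n = 3), and adjusted p-values are from limma.

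Toyocamycin-treated ILC2s had lower Il13, Il5 and Il4 transcripts, lower cell cycle and cholesterol synthesis transcripts, and higher transcripts of ribosomal proteins, p53 targets, heat shock proteins and autophagy genes than Control. Each list call behind these groups was lost when the correlation between genes was estimated (adjusted p = 0.57 to 0.732 with an estimated correlation), and that of heat shock genes also with quantile normalization (adjusted p = 0.0612, range 0.00172 to 0.0612). The result for ribosomal proteins is uncertain, because reads of near-identical copies may have been lost. Il13 was 6.95-fold lower, Xbp1 3.18-fold lower and the replication gene Rrm2 10.1-fold lower. Rora, a transcription factor needed for ILC2 development, was 13.1-fold higher and Ern1, which encodes IRE1, was 4.26-fold higher. Of 16223 genes tested, 5316 were higher and 5374 lower at an adjusted p under 0.05, which is 65.9% of the genes. A change of at least 2-fold was present in 2759 higher and 3329 lower genes. The groups did not overlap in 11209 genes (69.1%), where chance gives 10% for 3 against 3 samples. The edgeR test on the recovered reads called 4980 genes higher and 5329 lower among 12949 tested.

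The balance between higher and lower genes depended on how the samples were scaled. With the samples set to equal totals, 4040 genes were higher and 6897 lower, so that 36.9% of the calls were higher in place of 49.7%, and the median log2 change of all genes moved from −0.03 to −0.35. Directions of small changes are therefore relative to the deposited scaling.

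**Figure D1:**
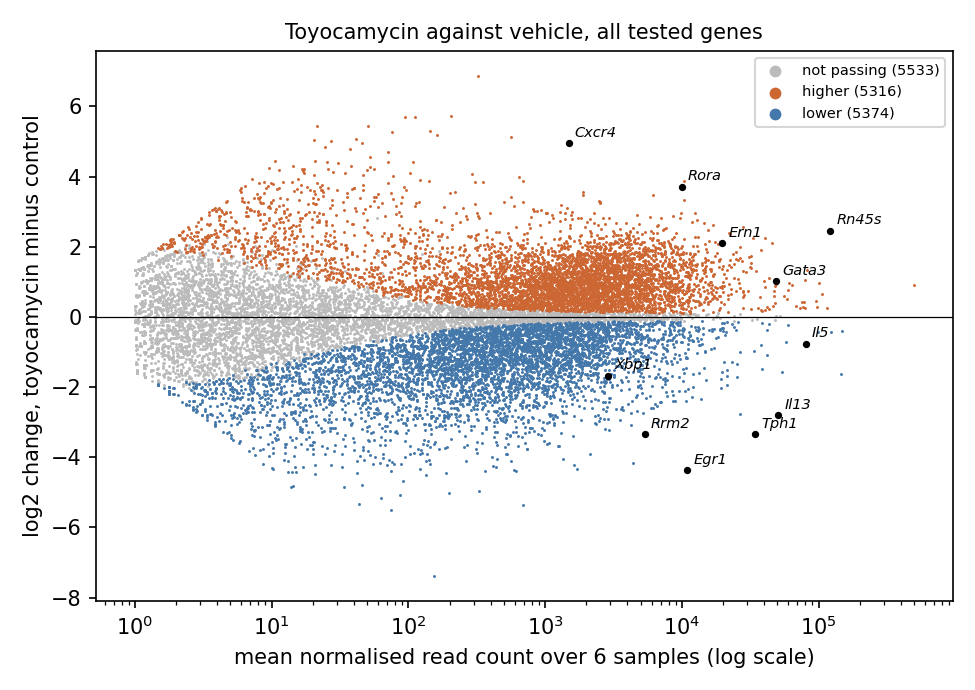
Log2 change between toyocamycin and Control (vertical axis) against the mean normalised read count over the 6 samples (horizontal axis, log scale), with 1 point per tested gene. Orange points are the 5316 higher genes, blue points the 5374 lower genes and grey points the 5533 genes that did not pass; with equal sample totals the colours would divide into 4040 and 6897.

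Among the genes named by size of change, the chemokine receptor Cxcr4 (chromosome 1, 128588199 to 128592299) rose 30.9-fold, from 92.96 ± 15.5 to 2874 ± 155 (log2 change 4.95, SE 0.11, adjusted p = 1.2e-18). The melanocortin receptor Mc5r reached 187.3 ± 16.9 from 2.944 ± 2.01, and Angptl1 reached 147.6 ± 37.7 from 2.954 ± 1.33. Col10a1, Hes2, Bach2, Hus1b, Kctd4 and the small nucleolar RNA gene Snord111 also rose, from Control means below the detection floor of 2.66. Lad1 had no read in Control and was at least 7.96-fold higher with toyocamycin. The most negative change was that of the citrate transporter Slc13a5 (chromosome 11, 72241990 to 72267295), from 308.1 ± 18.9 to 1.761 ± 3.05 (log2 change −7.39, SE 0.56, adjusted p = 1.58e-10, or −8.27 without toyocamycin replicate 1). The axonemal dynein gene Dnah8 fell 41-fold, from 1346 ± 96.8 to 32.79 ± 9.84, and the nuclease gene Ankle1 fell 31.9-fold, from 631.9 ± 28.9. Zranb3 fell 31.2-fold, and Kcnab3 and Rbm44 fell from 167.4 ± 11.8 and 121.9 ± 21.6 to 4.738 ± 3.9 and 3.455 ± 2.99. The log2 change of Rbm44 was −5.18, or −4.3 without toyocamycin replicate 3 and −5.63 without toyocamycin replicate 1. Slc13a5 and also Serpinb3a (147.1 ± 14.3 in Control), Disp2 (85.56 ± 14.5) and Ido1 (65.5 ± 11.2) fell to means below the detection floor of 3.38. Flywch2 had no read with toyocamycin and was at least 8.22-fold lower.

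Il13 (chromosome 11, 53631323 to 53634702) fell from 88690 ± 3300 to 12760 ± 1180 (log2 change −2.80, SE 0.061, adjusted p = 6.27e-19). Il5, on the same chromosome (53720794 to 53725103), fell less, from 101500 ± 2070 to 59660 ± 2130, or 1.7-fold (adjusted p = 4.4e-11). Il4 fell 2.7-fold, Csf2 1.83-fold and the epithelial growth factor gene Areg 2.52-fold. Il6 fell 14.6-fold, from 221.7 ± 16.2 to 15.22 ± 0.639, and the chemokine gene Ccl3 fell from 38.33 ± 10.5 to a level below the floor. Tph1, which encodes the enzyme that starts serotonin synthesis, fell 10.2-fold from 62480 ± 1290 to 6158 ± 331, and Osm had a log2 change of −2.38 and Lif of −1.25. Il3, at 10.08 ± 2.26 in Control, had no read with toyocamycin and was at least 2.98-fold lower. Calca, which encodes the neuropeptide CGRP, rose with a log2 change of 1.44. Il9 had a log2 change of 0.25 (SE 0.097, adjusted p = 0.0262), which turned to −0.09 with equal totals. Its call ended without Control replicate 1 (0.23), Control replicate 2 (0.18), toyocamycin replicate 1 (0.26) or toyocamycin replicate 2 (0.21).

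Of 21 measured ILC2 cytokines and effectors, 12 were lower, 6 higher and 3 did not pass; adjusted over the list alone, 13 were lower and 6 higher, and with equal totals 13 were lower and 2 higher. The list median was −0.87, or −0.77 with genes at 0 in a group set to their bound. Camera placed the list below other genes (adjusted p = 0.0116), but not with an estimated correlation (adjusted p = 0.678 with an estimated correlation).

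**Figure D2:**
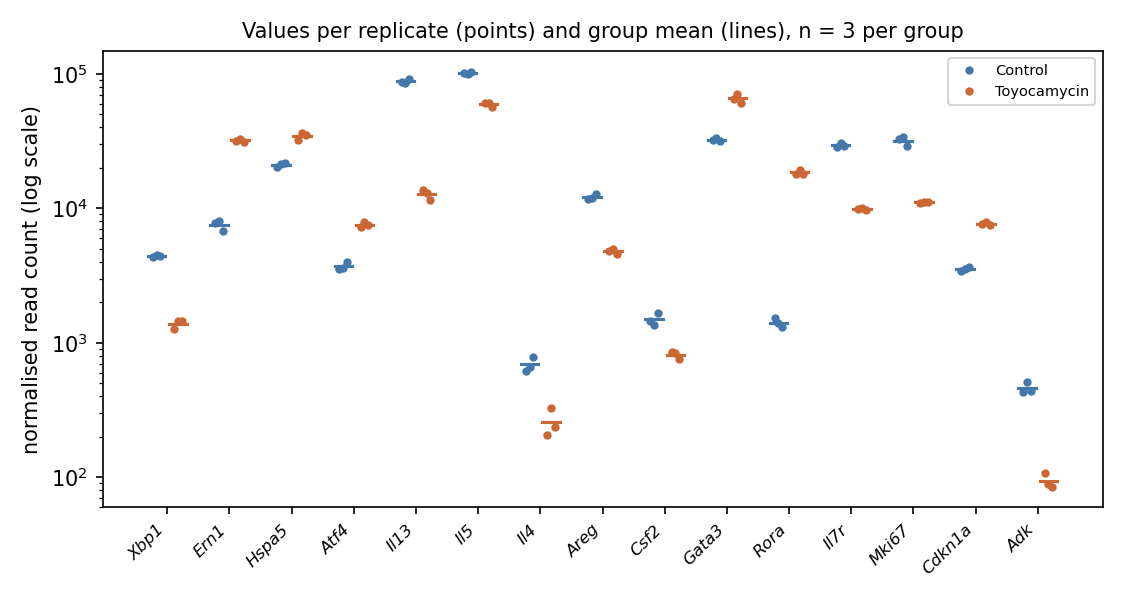
Normalised read counts (vertical axis, log scale) of 15 genes in each of the 3 Control (blue) and 3 toyocamycin (orange) samples; points are samples and lines are group means. Il13 went from a mean of 88690 to 12760 and Rora from 1414 to 18480, with no overlap between the groups.

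Genes of ILC2 identity moved in both directions. Rora (chromosome 9, 68653404 to 69388246) rose from 1414 ± 117 to 18480 ± 711 (log2 change 3.71, SE 0.06, adjusted p = 1.58e-20). Gata3, the transcription factor that defines ILC2s and Th2 cells, rose 2.02-fold from 32470 ± 676 to 65660 ± 5330. The Notch target Hes1 rose 10.6-fold and the transcription factor Ets1 had a log2 change of 1.40. Cytokine receptor transcripts fell for Il7r (2.98-fold, from 29470 ± 1020 to 9876 ± 217), Il9r (6.15-fold) and Il2ra (log2 change −1.57), and the leukotriene receptor gene Ltb4r1 fell with a log2 change of −2.58. The IL-33 receptor gene Il1rl1 was 1.2-fold higher (104900 ± 2030 against 126000 ± 4590), but its direction depended on the processing. The log2 change was −0.09 with equal totals (adjusted p = 0.00682) and −0.19 after GC and length correction (adjusted p = 4.49e-05), so the gene was called lower in both. The IL-25 receptor gene Il17rb had a log2 change of −0.29 (SE 0.11, adjusted p = 0.0321), which became 0.07 with quantile normalization. That call ended without Control replicate 1 (−0.31), 2 (−0.26) or 3 (−0.28) and without toyocamycin replicate 1 (−0.24) or 3 (−0.25). Of 27 identity genes, 14 were higher, 9 lower and 4 did not pass (10 higher and 12 lower with equal totals), with the same counts adjusted over the list alone. The list did not differ from other genes (median 0.26, or −0.09 with equal totals; camera adjusted p = 0.772), and the direction of fry was lower where the median, the mean and camera were higher.

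In the unfolded protein response, the sensor and its target moved apart. Xbp1 (chromosome 11, 5520641 to 5525993) fell from 4416 ± 73 to 1388 ± 111 (log2 change −1.67, SE 0.063, adjusted p = 1.36e-15). Ern1 (chromosome 11, 106397620 to 106487796) rose from 7503 ± 675 to 32000 ± 903 (log2 change 2.10, SE 0.059, adjusted p = 1.56e-17). Counts per gene do not separate the spliced from the unspliced form of Xbp1. The chaperone gene Hspa5 rose 1.63-fold, from 21130 ± 777 to 34510 ± 1850. Of 32 XBP1s targets, 15 were lower, 7 higher and 10 did not pass (25 lower and 3 higher with equal totals), with the same counts adjusted over the list alone. Edem2, which acts in the disposal of misfolded glycoproteins, fell 3.04-fold, Kdelr3 2.85-fold, and Srpr, a subunit of the signal recognition particle receptor, 2.71-fold. Spcs2 had a log2 change of −1.20 and Derl1 one of 1.20. The list as a whole did not pass (median −0.13, camera adjusted p = 0.17), but it was lower with equal totals (median −0.48, adjusted p = 0.00204) and with quantile normalization (median −0.46, adjusted p = 3.33e-05), over a range of 3.33e-05 to 0.286. With the deposited scaling it had an adjusted p = 0.998 with an estimated correlation.

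ATF6 targets had 8 lower and 1 higher member of 12, adjusted over all genes and adjusted over the list alone. Hyou1 fell 1.89-fold and Sel1l 1.84-fold, and Hspa5 was the member that rose. The ATF6 list shares 5 members with the XBP1s targets, Hyou1 and Sel1l among them, and also holds Xbp1. Its result is therefore not separate from that of the XBP1s targets. The ATF6 list fell just short of the threshold (median −0.26, camera adjusted p = 0.0538, and adjusted p = 0.739 with an estimated correlation). Its adjusted p ranged from 5.41e-05 to 0.091 in the alternatives and was 0.00343 with equal totals (11 of 12 lower), 5.41e-05 with quantile normalization, 0.028 after GC and length correction, 0.0388 without a filter, 0.0437 with the replicate block, 0.0348 without Control replicate 1, 0.0497 without Control replicate 2 and 0.0268 without toyocamycin replicate 2. Of 11 transcripts reported as direct substrates of IRE1 cleavage (RIDD), 4 were lower, 1 higher and 6 did not pass, also when adjusted over the list alone. Bloc1s1, the substrate most often used as a marker, fell 4.92-fold from 320.8 ± 51.7 to 65.2 ± 11.4. Hgsnat fell 3.61-fold and the integrin gene Itgb2 3.31-fold. Less cleavage by IRE1 would by itself leave more of its substrates, so these falls do not show it. Their cause was not tested. The RIDD list did not differ from other genes (median −0.14, camera adjusted p = 0.253).

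The integrated stress response was divided. Atf4 rose 2.04-fold, from 3705 ± 267 to 7560 ± 307, and Cebpb rose from 21.49 ± 17.9 to 204.7 ± 149. The log2 change of Cebpb was 3.24, or 2.69 without toyocamycin replicate 3 and 3.86 without Control replicate 3. Chac1 fell 8.95-fold and the cystathionine lyase gene Cth 8.4-fold, and Pck2 had a log2 change of −2.69. Ddit3, which encodes CHOP, had a log2 change of 0.37 (SE 0.13, adjusted p = 0.0154). That call ended with equal totals (0.02) and without Control replicate 1 (0.33), toyocamycin replicate 1 (0.32) or toyocamycin replicate 2 (0.32). Of 30 genes, 14 were higher and 14 lower, also when adjusted over the list alone (9 higher and 17 lower with equal totals). The median was 0.11, or −0.24 with equal totals and −0.37 with quantile normalization, while the mean was −0.26 and camera's direction was lower (adjusted p = 0.997).

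Proliferation genes fell as a group. All 26 S phase and DNA replication genes were lower (median −2.22), also when adjusted over the list alone. The thymidine kinase gene Tk1 fell 11.9-fold from 1305 ± 31.8 to 109.5 ± 26.3, the chromatin assembly gene Chaf1b 10.5-fold, and Rrm2 10.1-fold from 9718 ± 41 to 958.6 ± 140. The helicase gene Mcm2 had a log2 change of −2.40 and Cdc45 of −3.22. Camera gave an adjusted p of 2.44e-13 for the list, and an adjusted p = 0.57 with an estimated correlation. Of 25 G2 and mitosis genes, 23 were lower, 1 was higher and 1 did not pass, with the same counts adjusted over the list alone. Mki67 fell 2.87-fold from 31950 ± 2670 to 11130 ± 129, Top2a 5.08-fold, Ccna2 3.83-fold and Nusap1 3.38-fold. The median was −1.16 (camera adjusted p = 1.84e-08; adjusted p = 0.57 with an estimated correlation). Of 7 measured replication-dependent histone genes 6 were lower, among them H1f2 (5.24-fold), H3c1 and H4c4, and H2bc4 was higher with a log2 change of 1.88. H3c1 and H4c4 fell to means below the floor of 3.38. With 1 sample left out, the log2 change of H3c1 (−3.62) ran from −4.04 to −2.97 and that of H4c4 (−2.52) from −3.01 to −1.81. The histone list did not pass (median −1.85, camera adjusted p = 0.232).

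Among p53 targets, the cell cycle inhibitor gene Cdkn1a rose 2.16-fold from 3563 ± 115 to 7686 ± 160, Pmaip1, which encodes the pro-apoptotic protein NOXA, 6.11-fold from 680.3 ± 79.7 to 4156 ± 290, Perp 12.1-fold and Eda2r 6.26-fold. Zmat3 had a log2 change of 2.53 and Mdm2 of 1.34. Of 26 targets, 16 were higher, 5 lower and 5 did not pass, also when adjusted over the list alone (median 0.79, camera adjusted p = 0.0062). The call was lost when the correlation was estimated (adjusted p = 0.732 with an estimated correlation). With equal totals 15 were higher and 8 lower (median 0.44), and the median was 0.20 after GC and length correction (adjusted p = 0.0274, range 0.00374 to 0.0274). Of 22 measured apoptosis regulators, 8 were higher and 12 lower, also when adjusted over the list alone (5 and 15 with equal totals), without a shift of the list (median −0.17, camera adjusted p = 0.782). The inhibitor gene Birc3 fell 5.37-fold.

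Of 76 cytosolic ribosomal protein genes, 67 were higher, 1 lower and 8 did not pass, also when adjusted over the list alone (median 0.78); with equal totals 51 were higher and 9 lower. Rpl13 rose 6.6-fold, Rpl5 4.88-fold and Rpl38 4.78-fold, from low Control values of 62.66 ± 5.34, 184.1 ± 10.2 and 26.01 ± 11.4. Reads of these genes may have been lost to near-identical copies, so the folds and the list result are uncertain. Camera gave an adjusted p of 6.67e-10 (adjusted p = 0.678 with an estimated correlation). Of 36 ribosome biogenesis genes, 26 were higher and 8 lower, also when adjusted over the list alone, with Gnl3 up 3.58-fold from 1612 ± 107 to 5775 ± 172, Wdr43 2.85-fold and Rrs1 2.85-fold. Their median was 0.40 (camera adjusted p = 0.00443; adjusted p = 0.739 with an estimated correlation), and the call ended with equal totals (16 higher and 10 lower, median 0.05, adjusted p = 0.0707) and with quantile normalization (adjusted p = 0.179), in a range of 0.00222 to 0.179. The gene for the 45S precursor of ribosomal RNA, Rn45s, rose 5.14-fold from 39580 ± 18800 to 203400 ± 42500 (log2 change 2.46, SE 0.22, adjusted p = 1.62e-09). It took 0.169% ± 0.083 of the reads in Control and 0.68% ± 0.137 with toyocamycin.

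Mitochondrially encoded mRNAs were 2.79% ± 0.045 of the reads in Control and 3.80% ± 0.021 with toyocamycin. Of 13, 12 were higher and 1 did not pass, also when adjusted over the list alone; with equal totals 6 were higher and 1 lower (median 0.35). ND5 rose 1.96-fold from 68290 ± 1780 to 133900 ± 9920, ND6 2.01-fold and ND3 2.4-fold. The median was 0.69 (camera adjusted p = 0.00443; adjusted p = 0.57 with an estimated correlation). After a correction for GC content and length the median was −0.09 and the call ended (adjusted p = 0.971), in a range of 0.00136 to 0.971; ND3 then had a log2 change of 0.14 and ND6 of 0.08, and neither passed. In Control, COX1 had 343293 and COX2 160 normalised reads and Gapdh had 283 where Actb had 142275, so genes with near-identical copies elsewhere in the genome, ribosomal protein genes included, are uncertain. Both mitochondrial ribosomal RNAs rose, mt-Rnr1 3.06-fold and mt-Rnr2 2.53-fold.

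Cholesterol genes fell. Nsdhl, an enzyme of sterol synthesis, fell 12.1-fold from 814.4 ± 33.1 to 67.19 ± 27.2, and the mevalonate kinase gene Mvk 6.88-fold. Of 20 cholesterol synthesis and uptake genes, 16 were lower, 3 higher and 1 did not pass, also when adjusted over the list alone (median −0.82; 17 lower and 1 higher with equal totals). Camera gave an adjusted p of 0.000586 (adjusted p = 0.57 with an estimated correlation). Genes of adenosine handling had 7 lower and 3 higher members of 12, also when adjusted over the list alone (9 and 1 with equal totals). Adk, the adenosine kinase that phosphorylates adenosine analogues, fell 4.9-fold from 460.9 ± 44.2 to 94.07 ± 12.5 (adjusted p = 1.88e-11), Dck fell 2.98-fold, the transporter gene Slc28a2 3.17-fold, and the nucleoside transporter gene Slc29a1 and Ahcy had log2 changes of −1.38 and −1.50. That list did not pass (median −0.79, camera adjusted p = 0.148).

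Glycolysis genes were 9 higher and 9 lower of 20, or 5 and 12 with equal totals (median −0.06, camera adjusted p = 0.857), with the glucose transporter gene Slc2a3 3.87-fold lower and Pfkm 2.66-fold lower. Gapdh was 3.8-fold higher, from 283 ± 38.7 to 1077 ± 55.8, and is uncertain because of its near-identical copies. Of 45 nuclear-encoded oxidative phosphorylation genes, 18 were higher and 17 lower, or 8 and 26 with equal totals (median −0.36). The succinate dehydrogenase gene Sdhb fell 2.12-fold and the complex I gene Ndufs3 2.14-fold, while Cox7a2 rose from 1.482 ± 0.524, below the floor, to 29.4 ± 1.82. The median of that list was −0.01 and its mean 0.05, with camera's direction lower (adjusted p = 0.857). NRF2 targets had 7 higher and 6 lower members of 15, or 6 and 8 with equal totals (median 0.10, or −0.25 with equal totals and −0.38 with quantile normalization; camera adjusted p = 0.782). Among them Gclc, the catalytic subunit of glutathione synthesis, rose 3.44-fold and the ferritin gene Fth1 had a log2 change of 1.00, while Nqo1 fell 4.49-fold and Srxn1 2.56-fold. The counts of these lists were the same adjusted over the list alone.

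Heat shock genes rose, 11 of 13, with 1 lower and 1 not passing, also when adjusted over the list alone (median 0.87; 8 higher and 2 lower with equal totals). The co-chaperone gene Bag3 rose 3.24-fold from 1146 ± 42.3 to 3718 ± 192 Hspa1b 4.46-fold and Hspa1a from 3.53 ± 3.02 to 38.25 ± 16, while the constitutive Hspa8 had a log2 change of −0.81. Camera gave an adjusted p of 0.00349 (adjusted p = 0.678 with an estimated correlation), which was 0.0612 with quantile normalization and ranged from 0.00172 to 0.0612. Of 20 autophagy and lysosome genes, 14 were higher, 3 lower and 3 did not pass, also when adjusted over the list alone (median 0.94; 12 higher and 6 lower with equal totals). Gabarapl1 rose 5.9-fold, Atg12 3.95-fold and Map1lc3b, which encodes the autophagosome protein LC3B, 3.59-fold from 1723 ± 88.8 to 6183 ± 435, and Lamp1 had a log2 change of 1.40. Camera gave an adjusted p of 0.00295 (adjusted p = 0.678 with an estimated correlation).

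Interferon-stimulated genes were lower in 14 of 25, with 11 not passing, also when adjusted over the list alone (median −0.94). The nucleic acid sensor gene Zbp1 fell 7.87-fold from 1073 ± 13.7 to 136.2 ± 24, Gbp2 6.38-fold and Rtp4 5.3-fold. Camera gave an adjusted p of 0.00443 (adjusted p = 0.57 with an estimated correlation). Immediate early and short-lived transcripts moved apart. Egr1 (chromosome 18, 34861207 to 34864956) fell 20.8-fold from 20750 ± 796 to 999.2 ± 45 (log2 change −4.37, SE 0.054, adjusted p = 3.92e-22), and Fos had a log2 change of −2.66. The nuclear receptor gene Nr4a1 rose 9.94-fold and Tnfaip3, an inhibitor of NF-kB signalling, 7.77-fold from 2823 ± 99.2 to 21940 ± 855. Of 30 such genes, 17 were lower, 11 higher and 2 did not pass, also when adjusted over the list alone (18 lower and 7 higher with equal totals; median −0.54, camera adjusted p = 0.253). With quantile normalization the adjusted p was 0.0398, in a range of 0.0398 to 0.924.

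**Figure D3:**
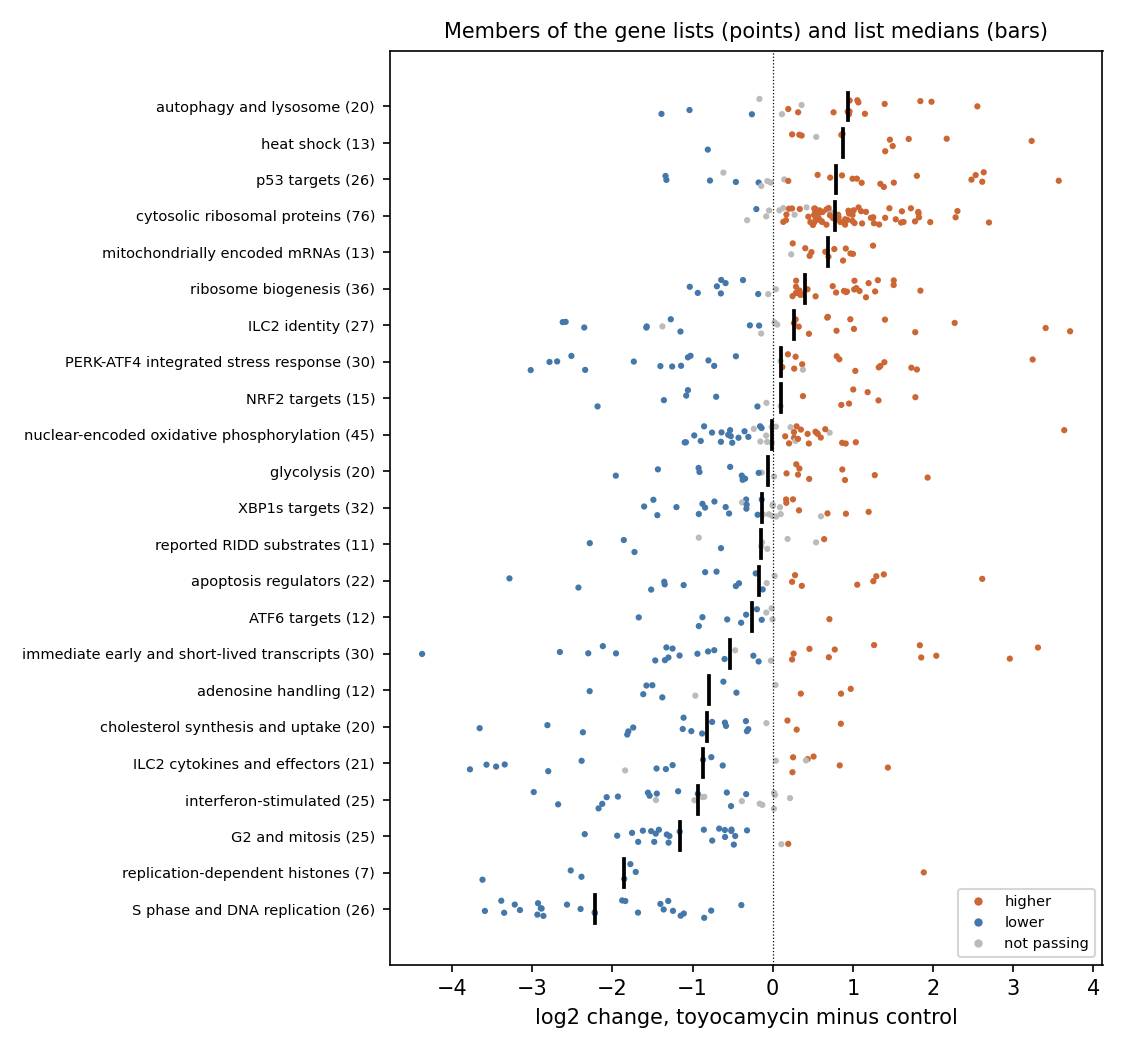
Log2 change (horizontal axis) of each measured member of 23 gene lists (number of measured members in brackets); orange points are higher, blue points lower and grey points did not pass, and black bars are list medians. List medians run from −2.22 for S phase and DNA replication to 0.94 for autophagy and lysosome; the medians of the integrated stress response and NRF2 targets fall below 0 with equal totals and with quantile normalization, and that of ILC2 identity with equal totals.

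Markers of other cell types were mostly low, and camera called 0 of the 8 lists (adjusted p from 0.772 to 0.997, unadjusted p from 0.475), while fry called T cell markers higher (adjusted p = 0.00489) and NK cell and ILC1 markers lower (adjusted p = 0.00211). Of 72 measured markers, 11 were higher and 15 lower. T cell markers were 4 higher and 3 lower of 12 (2 and 3 with equal totals), with the costimulatory receptor gene Cd28 3.06-fold higher from 4298 ± 118 to 13130 ± 721 and Cd3e 5.74-fold lower from 35.17 ± 0.778 (list median 0.30). Cd3d had a log2 change of −2.17, which did not pass without Control replicate 2 (−1.81), toyocamycin replicate 2 (−1.86) or toyocamycin replicate 3 (−1.86). ILC3 markers were 2 higher and 2 lower of 7, with Il22 2.64-fold lower, Lta 2.99-fold higher and Il17a 1.8-fold higher, the last not passing after GC and length correction (log2 change 0.44). NK cell and ILC1 markers were 2 higher and 2 lower of 8. They include Gzmb, which was among the most abundant transcripts here and fell 3.08-fold from 219700 ± 5190 to 71360 ± 3720, Gzma, with a log2 change of 0.48, and the perforin gene Prf1, which fell 5.25-fold. Il12rb2 had a log2 change of 2.00, which did not pass without Control replicate 1 (1.32). Their median was −0.26, or 0.17 with a gene at 0 in a group set to its bound. B cell and plasma cell markers were 2 lower of 9, Cd79b (2.13-fold) and Ighm (2.01-fold), with a list median of −0.22.

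Macrophage and dendritic cell markers were 2 higher and 1 lower of 14, or 1 higher adjusted over the list alone and 1 and 1 with equal totals, with the chemokine receptor gene Ccr2 3.8-fold lower from 11850 ± 320 to 3119 ± 122 and Cd68 1.51-fold higher. H2-Ab1 was 1.52-fold higher (log2 change 0.61), which did not pass with equal totals (0.26) or without Control replicate 2 (0.44), Control replicate 3 (0.59) or toyocamycin replicate 1 (0.43). The median of that list was 0.53 and its mean 0.11, while camera's direction was lower. Mast cell markers were 1 higher and 2 lower of 5, and Kit rose 1.49-fold from 29820 ± 803 to 44480 ± 1970. Cpa3 and Hdc were lower with log2 changes of −1.78 and −1.08, and neither call held without Control replicate 1 (−1.70 and −1.06), Control replicate 3 (−1.51 and −0.96), toyocamycin replicate 2 (−1.94 and −0.92) or toyocamycin replicate 3 (−1.23 and −0.77). Their median was −1.01, or −0.35 with a gene at 0 in a group set to its bound, and the direction of fry was higher. Epithelial cell markers were 1 lower of 8, with Lgals4 3.89-fold lower from 152.1 ± 35.3 (list median −0.12, or 0.20 with quantile normalization). Fibroblast and endothelial cell markers were 2 lower of 9, with Pecam1 1.79-fold lower from 1012 ± 39.7 to 565 ± 40.5 and Col1a2 1.99-fold lower (list median −0.11, or 0.36 with quantile normalization); Col1a2 did not pass with quantile normalization (log2 change −0.44). The direction of fry was higher for ILC3 markers too, where the median (−0.46), the mean and camera were lower.

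Camera called 11 of the 31 lists, 6 higher and 5 lower. With an estimated correlation 0 of the 11 calls held and the lowest adjusted p was 0.57, with 1 list (S phase and DNA replication) at an unadjusted p under 0.05. That test was also weaker where the estimate was close to the preset. For adenosine handling (estimate 0.011) camera's unadjusted p went from 0.0623 to 0.136. With an estimated correlation, camera refers its statistic to the 4 residual degrees of freedom of the fit, which makes it weaker with so few samples. The lost calls therefore cannot be put down to correlation between genes alone. A lost call does not by itself show that a list did not shift. Fry, which does not compare a list with other genes, called all 11 in the direction of camera. The counts of higher and lower members were the same adjusted over the list alone for 29 of the 31 lists.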

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

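The GC and length correction and the edgeR and DESeq2 counts were chosen after the data were seen; the other alternatives were planned. Over 21 alternatives the count of higher genes ran from 4040 to 5359 and that of lower genes from 4996 to 6897, all within 1.5 times of 5316 and 5374. Leaving out each sample in turn gave 5042 to 5242 higher and 4996 to 5269 lower genes, and 2613 to 2753 higher and 3144 to 3327 lower at 2-fold. The count of genes at least 2-fold higher fell from 2759 to 1777 with equal totals; there the median log2 change of all genes moved by its own construction from −0.03 to −0.35, and genes at least 2-fold lower rose in number from 3329 to 4438. Of the calls made with the deposited scaling, 163 turned to the opposite direction with equal totals, 225 with quantile normalization and 176 after GC and length correction. DESeq2 called 5139 genes higher and 5024 lower.

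Camera's 6 higher and 5 lower lists became 0 and 0 with an estimated correlation, where the test rests on 4 residual degrees of freedom. Quantile normalization gave 4 higher and 8 lower lists, and the cause was not tested. Fry gave 8 higher and 13 lower lists. It does not compare a list with other genes, and 65.9% of all genes tested were called changed. With 1 sample left out there were 6 higher and 5 to 6 lower lists.

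Of 131 genes tested under the alternatives, 117 kept their direction and their side of the threshold in each alternative that gave them a value and 14 did not; 4 genes, Il3 and Rn45s among them, had no value in at least 1. Il9 (log2 change 0.25) turned to −0.09 with equal totals, −0.14 after GC and length correction, and −0.14 with that correction and the replicate block. Il1rl1 (0.26) turned to −0.09, −0.19 and −0.19 in the same alternatives and was 0.00 with quantile normalization, where Il17rb (−0.29) was 0.07. The cause was not tested.

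The replicate numbers are shared by the groups, but same-numbered samples did not deviate together (correlations −0.043, 0.068 and −0.139). Differently numbered pairs ran from −0.22 to 0.211, a range that holds these values. So few pairs cannot tell whether a shared number marks a shared preparation. With a replicate block 5272 genes were higher and 5298 lower, and 2728 and 3288 at 2-fold. Among the named genes and lists the block changed the call of Cpa3 and of ATF6 targets (adjusted p = 0.0437). Depth limits the genes near the floor of 2.66 to 3.38 normalised reads.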

Other observations

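The tests on symbol families, on GC content by gene and on small nucleolar RNA genes were chosen after the results were seen, and so was the use of the full spread in the tests on mitochondrial ribosomal RNAs and short-lived transcripts; the other tests weighed here were written before theirs. Camera was run on 27 symbol families adjusted together, with an adjusted p of 0.445 to 0.962 with an estimated correlation. Fanconi anaemia genes, which act in the repair of DNA crosslinks, were lower in 8 of 9 (median −2.0, adjusted p = 0.00169; adjusted p = 0.445 with an estimated correlation). Subunits of the replicative DNA polymerases were lower in 9 of 10 (median −2.07, adjusted p = 7.86e-05; adjusted p = 0.445 with an estimated correlation), and tubulin genes in 9 of 13 (median −0.91, adjusted p = 0.0101; adjusted p = 0.445 with an estimated correlation). Of 11 Srsf genes 9 were higher (median 0.68, adjusted p = 0.00511) and of 21 Hnrnp genes 15 (median 0.66, adjusted p = 0.00169), both with an adjusted p = 0.535 with an estimated correlation. The Prpf genes, a further splicing family, were 10 higher and 3 lower of 13 and did not pass (median 0.54, adjusted p = 0.0613; adjusted p = 0.582 with an estimated correlation). Translation factors of the Eif family were 37 higher and 9 lower of 55 (adjusted p = 0.000144, 34 and 17 with equal totals). Ubiquitin-conjugating Ube2 genes were 27 higher and 4 lower of 34 (adjusted p = 0.000144), and deubiquitinase Usp genes 32 higher and 6 lower of 51 (adjusted p = 0.000483). RING finger Rnf genes were 41 higher and 18 lower of 74 (adjusted p = 0.0031, 37 and 25 with equal totals). The Eif, Ube2, Usp and Rnf families each had an adjusted p = 0.535 with an estimated correlation. Klhl genes were 14 higher and 6 lower of 30, or 13 and 9 with equal totals (adjusted p = 0.0499, and adjusted p = 0.496 with an estimated correlation). The medians of these families kept their sign with equal totals and with quantile normalization. Gimap genes, GTPases of lymphocytes, were 6 lower and 3 higher of 9 and did not pass (adjusted p = 0.0743).

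Small nucleolar RNA genes were higher in 40 of 94 and lower in 0, with 54 not passing (median 1.12, or 1.10 with genes at 0 in a group set to their bound; camera adjusted p = 0.0647). With equal totals 33 were higher and 1 lower. MicroRNA genes were higher in 28 of 98 and lower in 2 (camera adjusted p = 0.21). Most of these genes lie inside a longer gene. For 83 small nucleolar RNA genes, a single measured host gene lay on the same strand, with 62 hosts in all. The median log2 change of these small RNA genes was 1.16 against 0.79 for the hosts. The median difference within pairs was 0.26, and 51 of the 83 had a log2 change above that of their host. For 64 microRNA genes in 59 hosts the medians were 0.81 and 0.54. The median difference within pairs was 0.42, and 39 of these microRNA genes had a log2 change above that of their host. Fragments of the unspliced host and the small RNA cannot be separated in counts per gene.

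The log2 change fell with the GC content of the transcript across 9821 genes with a mean of at least 100 (Spearman −0.272; genes are not independent replicates), where GC content and length together accounted for 7.5% of the variance. The median was 0.70 in the decile of lowest GC content (33% to 41.6%) and −0.37 in the decile of highest (57.9% to 71.1%). All 3 Control samples had a slope of 0.253 to 0.261 log2 units per 10% of GC relative to the mean of the samples, and all 3 toyocamycin samples one of −0.239 to −0.266. Slopes relative to that mean must balance, so the opposite signs are 1 contrast between the groups and not separate results.

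For the breadth of the response, after each sample's trend on GC content and length was removed, 95.7% of the 2-fold calls stayed called in their direction and 79.4% were still 2-fold, against 96.5% and 80% with quantile normalization. Both argue against the trend or the scaling as the whole cause. Equal totals move all genes down by a similar amount, too small to turn a 2-fold change; genes at least 2-fold higher numbered 1777 there against 2759. With 3 against 3 samples the 10 splits are too few to give a share under 0.05: the real split called 10690 genes in limma and the highest of the others 0 (117 to 241 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. Each other split puts samples of both groups on each side, so differences between the groups widen the spread within its sides. A low count follows from this and does not weigh against chance. An effect of the treatment stays open, as a hypothesis.

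The higher Rn45s was set against less complete removal of ribosomal RNA from the toyocamycin libraries, under which both mitochondrial ribosomal RNAs would rise by at least 1.23. Against this bound mt-Rnr1 rose by 1.61 and mt-Rnr2 by 1.34, which is 0.11 above it with an SE of 0.12; with equal totals mt-Rnr2 rose by 0.99, below the matching 1.05. For more RNA without a poly(A) tail, the median of the small nucleolar RNA genes was 1.12 (bootstrap SE 0.18), also too close to 1.23 to decide. Neither explanation can be excluded, and the spread of Rn45s and of these RNAs keeps both open. Slower processing of the precursor, for which toyocamycin is known, stays open and was not tested, since counts per gene do not separate precursor from mature RNA.

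Lower Xbp1 with higher Ern1 was set against loss of short-lived transcripts in general. The immediate early and short-lived list had a median of −0.54, above the −1.67 of Xbp1 by more than 2 SE of the median (bootstrap SE 0.36), the bound written first. That bound was too narrow, since the members go both ways with an SD of 1.70, wider than the distance to Xbp1. Lower activity of spliced XBP1 may be involved, as a hypothesis: the median of its targets was −0.129, but the test did not pass with the deposited scaling and passed with equal totals (25 of 32 lower and 3 higher, median −0.48, adjusted p = 0.00204, range over the alternatives 3.33e-05 to 0.286), with an adjusted p = 0.998 with an estimated correlation. Neither can be decided here: members of the short-lived list go both ways, and the result for XBP1s targets depends on the scaling.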
